A study of Mus musculus with 6 samples.

How the data were processed

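Total RNA of Spot14 GFP positive and Spot14 GFP negative mouse neural stem cells, 3 biological replicates each per the labels, was extracted and labelled with biotin with commercial kits and hybridised to Affymetrix Mouse Genome 430 2.0 arrays. How the cells were grown or isolated, and how GFP positive and negative cells were separated, is not given in the sources used here. The deposited values are on a log2 scale and were made by the authors with GCRMA, per the submitters' processing notes; its version is not given in the sources used here. GCRMA subtracts a background estimated from probe sequence, normalizes arrays to a common distribution and summarises the probes of each probe set. It pulls dim probe sets toward a low floor, so that folds of genes near background depend on that estimate. It also assumes that the distribution of signal is alike on all arrays, so that a shift of all genes in 1 direction would not be seen. The deposited table held 6 columns, 1 per array, and no other columns, and its 45101 probe sets were used without further normalization.

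Probe sets were named from the platform annotation. Of 45101 probe sets 35890 had an annotation, 932 of those had several genes or no symbol, and 34945 named exactly 1 gene after 13 annotated control probe sets were left out. Through their gene identifiers 34741 were found in the RefSeq annotation of mouse assembly GRCm38.p6, and 0 symbols needed an update. A genome build is not given in the sources used here and no coordinates were used. Each of 18193 genes was represented by the probe set with the highest mean over all 6 arrays. A gene was tested where at least 3 of 6 arrays, whatever their group, read log2 4 or more, which left 10531 genes. Among genes past the threshold, 136 had several probe sets above that level, and 3 of these had 1 or more probe sets of opposite sign; none of the genes named by rule is among them.

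The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Differences are GFP positive minus GFP negative on the log2 scale, and intervals are 95% limma intervals. The test was tried on simulated data for this comparison of 10531 genes with 50 genes changed at each size. It recovered 4% of changes of 0.5, 22% of changes of 1, 80% of changes of 2 and 86% of changes of 3 on the log2 scale. It made 5 false calls, and 0 calls where nothing was changed. The simulated noise was independent between genes and of equal spread on all arrays. The real arrays differed more, as GFP negative replicate 3 stood apart, so these false calls give no rate for the real data. Even in the simulation, smaller differences were mostly missed at this number of arrays.

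Before the data were examined, 34 gene lists with 704 members were fixed, covering lipid and energy metabolism, the cell cycle, cell types of the brain, signalling, interferon and stress responses, ribosomal proteins, extracellular matrix and sex-linked genes; 653 members had a probe set. The 28 lists with at least 5 tested genes were tested with camera at the preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over these lists. Of them 14 passed, 9 higher and 5 lower. With a correlation estimated per list 1 passed, the astrocyte markers, and with fry 14 passed for a shift in 1 direction and 18 for change in either direction; fry does not compare a list with other genes. The estimated correlation was −0.042 for intermediate progenitors and −0.010 for the immediate early list, below the preset 0.01. Both lost their call with the estimate, so a higher correlation does not account for these losses, and their cause was not tested. For the other lists that lost their call the estimate was above 0.01, up to 0.55 for mitosis. Counts of members are given over all genes tested and adjusted over the list alone. Of the tested genes 24 stand on more than 1 list, so the list tests are not independent; Gfap, Tnc, Fabp7, Aldoc, Egfr and Hes5 are such genes among those named.

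The genes named were chosen by a rule fixed beforehand: Thrsp first; the 15 genes with the largest difference in each direction among those past the threshold whose groups did not overlap, clone and predicted names left out; for each list described, up to 2 members per direction with the largest difference past the threshold or, if none passed, the 2 brightest; and a fixed set of metabolic, stem cell, lineage and cell cycle genes. Names that complete a count of few genes were added after their values were seen. Alternatives fixed beforehand were no filter or log2 6, quantile normalization or a common median, all probe sets or none with cross-hybridising suffixes, eBayes with trend and robust settings, array weights, the replicate number as a block, a 2-fold minimum and each array left out in turn. With all probe sets a named gene was read from its probe set with the smallest p, which favours a call. The mean 3′ minus 5′ difference of the Gapdh and beta-actin control probe sets was added as a covariate after seeing the data. No batch is given in the labels. Arrays compared in pairs held different values, and none was treated as a duplicate.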

Results

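Mouse neural stem cells carrying a green fluorescent protein (GFP) reporter of Spot14 were divided into GFP positive and GFP negative cells, and total RNA of each was hybridised to Affymetrix Mouse Genome 430 2.0 arrays. Spot14 is the product of Thrsp, a gene responsive to thyroid hormone that is known from lipogenic tissues. The series holds 6 arrays, 3 per group, which the labels call biological replicates. The title of the series places the comparison in the context of lipogenesis by fatty acid synthase (Fasn) in adult neural stem cells. The question taken here is which genes differ between cells with and without the Spot14 reporter signal. The median log2 value of an array was 3.55 to 3.67, and 47.4% to 48.2% of probe sets lay at or above log2 4. With 3 arrays per group, the number of arrays limits the precision.

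Genes of cell division were lower in GFP positive than in GFP negative cells, and astrocyte markers were higher. Of 25 measured mitosis genes, 22 fell, with a median difference of −1.76 on the log2 scale, or 3.39-fold lower (camera adjusted p = 4.25e-25 for the list; adjusted p = 0.192 with an estimated correlation). Of 20 measured astrocyte markers, 6 rose, with a median difference of 0.77, or 1.71-fold higher. Cholesterol synthesis genes were lower as a list (median −0.68, camera adjusted p = 6.25e-08; adjusted p = 0.251 with an estimated correlation). None of 19 measured fatty acid synthesis genes passed the test, Fasn included; at an unadjusted p under 0.05 limma counted 2 higher and 1 lower. Thrsp itself differed by 0.65, or 1.57-fold, toward GFP positive cells and did not pass the test (limma adjusted p = 0.0893).

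Thrsp was among the brightest signals on every array. Its brightest probe set measured 14.32, 14.20 and 14.13 on the GFP positive arrays and 13.58, 13.41 and 13.71 on the GFP negative arrays. The means were 14.21 ± 0.10 and 13.56 ± 0.15 (SD, n = 3 each), a difference of 0.65 (SE 0.17, 95% interval 0.25 to 1.05). All 3 GFP positive arrays lay above all 3 GFP negative arrays, yet the limma adjusted p of 0.0893 did not pass the threshold of 0.05. An exact 2-sided permutation test of the same values gave p = 0.1, the smallest that 3 against 3 allows. Another probe set read 12.42 ± 0.16 against 11.53 ± 0.27, which is 1.85-fold higher, and again separated the groups. In a fit of all probe sets above the filter it did not pass either (limma adjusted p = 0.0971). The remaining probe set lay near background, at 2.54 and 2.32. The difference in Thrsp was 0.72 without GFP negative replicate 3 and passed (limma adjusted p = 0.0331); the adjusted p ran from 0.0331 to 0.323 over the arrays left out in turn. With all 6 arrays at equal weight Thrsp passed with trend and robust settings (0.65, limma adjusted p = 0.0205). It also passed with array weights (0.70, 0.0144). These gave GFP negative replicate 3 a weight of 0.152 and GFP positive replicate 2 one of 8.35, so that fit comes near to leaving the former out. The limma adjusted p ran from 0.0144 to 0.336 over all alternatives.

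Among 10531 genes tested, 248 were higher and 222 lower in GFP positive cells at a limma adjusted p under 0.05, and 202 and 200 of these differed by at least 2-fold. The groups did not overlap for all 470 of these genes and for 2668 tested genes in all (25.3%, where chance gives 10%). For 40 of the higher and 48 of the lower genes, the mean of the dimmer group lay under log2 4, near background, so that their folds depend on the background correction. The counts depended on single arrays, and so do the calls of most genes named below. With GFP positive replicate 1 left out, 2 genes were higher (Shisa9 and, named after its value was seen, 2900052N01Rik) and 0 lower, with 760 higher and 702 lower at an unadjusted p under 0.05. With replicate 3 of that group left out, 1 gene was higher (Shisa9) and 0 lower, with 735 and 529 unadjusted. The counts were 40 higher and 66 lower without GFP positive replicate 2. They were 158 and 196 without GFP negative replicate 1, 70 and 36 without GFP negative replicate 2, and 801 and 443 without GFP negative replicate 3. All 470 genes kept their sign in each of these fits, which had to follow, since their groups do not overlap, and adds no support. Of the genes named below by rule only Shisa9 passed in all 6 fits. With the ratio of 3′ to 5′ signal of the control transcripts as a covariate, a fit chosen after seeing the data, 9 genes were higher and 0 lower, with 794 and 563 unadjusted.

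**Figure D1:**
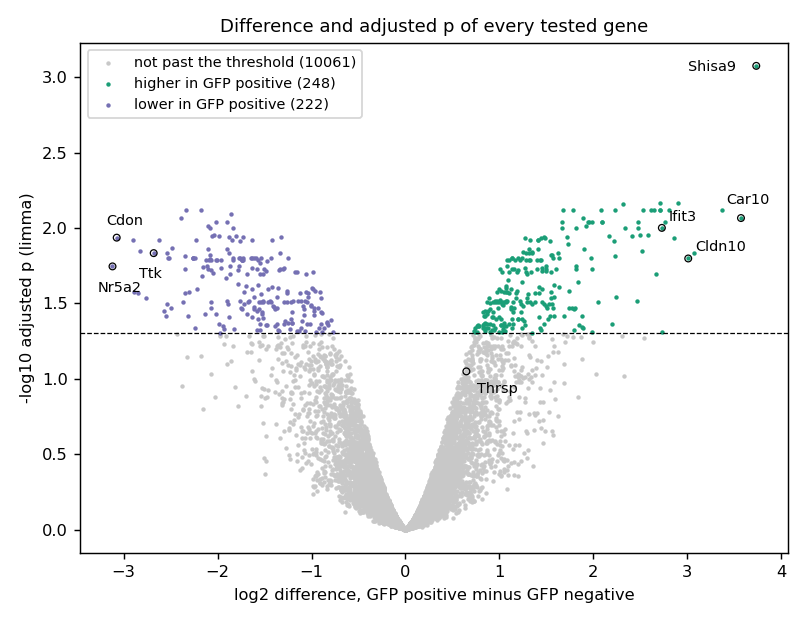
Difference between the groups (GFP positive minus GFP negative, log2, horizontal axis) and −log10 of the limma adjusted p (vertical axis) for each of the 10531 genes tested, 3 arrays per group. Coloured points are the 248 higher and 222 lower genes, the dashed line is an adjusted p of 0.05, and Thrsp (difference 0.65) lies under it.

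GFP negative replicate 3 stood apart from the other arrays. The first principal component of the tested genes (44.2% of the variance) separated the groups, with scores of −36.5 to −20.1 in GFP positive and 9.92 to 45.7 in GFP negative arrays. On the second component (36.3%) GFP negative replicate 3 scored 36.8, while the other GFP negative arrays scored −31.9 and −33.8. Across genes, which are not independent replicates, correlations between arrays were 0.985 to 0.993 within GFP positive, 0.952 to 0.982 within GFP negative and 0.935 to 0.972 between the groups. GFP negative replicate 2 had the largest excess of 3′ over 5′ signal, 2.33 for Gapdh and 2.65 for beta-actin on the log2 scale, against 1.14 to 1.65 and 1.77 to 2.03 on the other arrays. The signal of the middle 18S ribosomal RNA control was 12.8 to 13.0 in GFP positive and 13.4 to 14.1 in GFP negative arrays.

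**Figure D2:**
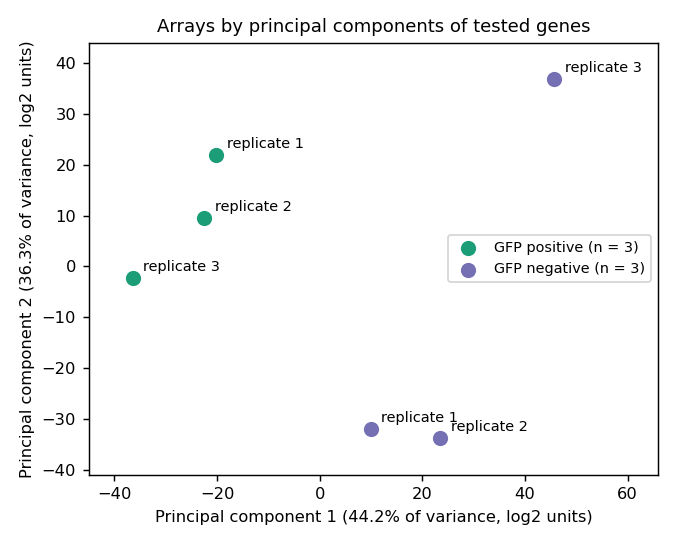
Scores of the 6 arrays on the first 2 principal components of the tested genes (log2 units; 44.2% and 36.3% of the variance), coloured by group. The groups separate along the horizontal axis, and GFP negative replicate 3 lies at 36.8 on the vertical axis, away from the other GFP negative arrays at −31.9 and −33.8.

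Mitosis genes formed the largest group of lower genes. All 25 measured members were negative, 22 fell after adjustment over all genes and 25 when adjusted over the list alone (camera adjusted p = 4.25e-25; adjusted p = 0.192 with an estimated correlation). Ttk, a kinase of the spindle checkpoint, was 6.41-fold lower (log2 −2.68, SE 0.37, limma adjusted p = 0.0147). Cenpe, a kinetochore motor, fell by 2.55, from 7.59 ± 0.83 in GFP negative to 5.04 ± 0.77 in GFP positive cells (SD, n = 3; limma adjusted p = 0.0383). Mki67, the proliferation marker Ki-67, was 4.29-fold lower (−2.10, SE 0.33, limma adjusted p = 0.0188), and Top2a, the topoisomerase of dividing cells, was 3.35-fold lower (−1.74, SE 0.26). Cenpf, another member, fell by 2.54. Outside the list, the lower genes Cdkn3 (−2.62), Spc24 (−2.53), Pimreg (−2.91) and Cdca7l (−2.52) are also known from dividing cells; Spc24 and Pimreg lay under log2 4 in GFP positive cells. The list varied among the arrays of a group as well: relative to each gene's mean, its median was −0.87, −0.60 and −1.30 on GFP positive replicates 1, 2 and 3, and 0.58, 0.88 and 1.29 on the GFP negative ones. The number of members past the threshold was 0, 10 and 0 without GFP positive replicate 1, 2 or 3, and 16, 3 and 23 without GFP negative replicate 1, 2 or 3. In each of those fits, and with the 3′ to 5′ covariate, where 0 passed, all 25 were negative at an unadjusted p under 0.05. Of the genes named here, none passed without GFP positive replicate 1 or 3. The calls of Cenpe, Mki67, Top2a and Spc24 were also lost without GFP positive replicate 2, and those of Ttk, Cenpe, Mki67, Top2a, Cenpf and Cdca7l without GFP negative replicate 2; the limma adjusted p was at most 0.137 in any of these fits.

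DNA replication genes were lower too, by a median of 1.07 on the log2 scale (2.09-fold). All 24 measured members were negative, and 8 fell after adjustment over all genes and 18 when adjusted over the list alone (camera adjusted p = 6.84e-15; adjusted p = 0.192 with an estimated correlation). Mcm5 and Mcm2, subunits of the replicative helicase, were 3.76-fold and 3.07-fold lower (limma adjusted p = 0.0214 and 0.0287). E2f1, a transcription factor of S phase entry, was 3.58-fold lower and lay under log2 4 in GFP positive cells (3.58 ± 0.19, SD, n = 3). The number of members past the threshold was 0, 4 and 0 without GFP positive replicate 1, 2 or 3 and 11, 1 and 12 without GFP negative replicate 1, 2 or 3; at an unadjusted p under 0.05 it was 18 and 17 where it was 0. Mcm5 did not pass without GFP positive replicate 1 or 3 or GFP negative replicate 2 (limma adjusted p at most 0.100), E2f1 without GFP positive replicate 1 or 3 (at most 0.0637), and Mcm2 passed only without GFP negative replicate 3 (otherwise at most 0.110). D-type cyclins did not pass: Ccnd1 differed by −0.55 (limma adjusted p = 0.136) and Ccnd2 by 0.08 (0.867).

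Genes of cell cycle exit and quiescence were higher as a list, with 20 of 24 positive and a median of 0.34 (camera adjusted p = 0.0183; adjusted p = 0.289 with an estimated correlation). No member passed the limma threshold, nor when adjusted over the list alone, and 5 were higher at an unadjusted p under 0.05. The brightest members were Lrig1 (0.46, SE 0.36) and Cdkn1a (−0.17, SE 0.20), and the cell cycle inhibitor Cdkn1b differed by 0.47 (limma adjusted p = 0.343). The list was past the threshold no longer without GFP negative replicate 3 (median 0.26, camera adjusted p = 0.235), and 1 member was lower. Cdkn1c lay near background in both groups (2.75 and 2.70).

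All 20 measured astrocyte markers were positive in GFP positive cells. After adjustment over all genes 6 rose (Gfap, Aqp4, Slc1a2, Ndrg2, Cldn10 and Slc6a11), and 14 did when adjusted over the list alone (camera adjusted p = 2.52e-11; adjusted p = 0.0442 with an estimated correlation). Cldn10, a claudin, was 8.07-fold higher (3.01, SE 0.44, limma adjusted p = 0.0159), from 3.71 ± 0.83, near background, to 6.72 ± 0.48 (SD, n = 3). Its only probe set above the filter carries a cross-hybridising suffix. Without such probe sets 19 markers were tested, Cldn10 not among them, and 5 rose. Slc6a11, a transporter of the neurotransmitter GABA, was 2.89-fold higher (1.53, SE 0.29, limma adjusted p = 0.0318). Gfap, the intermediate filament of astrocytes and radial glia-like stem cells, was 2.83-fold higher, at 11.76 ± 0.06 against 10.26 ± 0.41 (SD, n = 3; limma adjusted p = 0.0188). S100b differed by 1.20 and missed the threshold (limma adjusted p = 0.0936), which it passed without GFP negative replicate 3 (0.0201). The number of members past the threshold was 0 without any 1 of the GFP positive replicates, where 13, 11 and 10 were higher at an unadjusted p under 0.05, and 5, 3 and 9 without GFP negative replicate 1, 2 or 3. Slc6a11 also lost its call without GFP negative replicate 2 (limma adjusted p at most 0.136 over the arrays left out). The list stayed past the camera threshold in each of these fits.

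Of the 20 measured radial glia-like stem cell markers, 2 rose and 1 fell, and the list was higher (median 0.49; camera adjusted p = 0.0195; adjusted p = 0.251 with an estimated correlation). When adjusted over the list alone, 3 were higher and 1 lower. Nr2e1, a nuclear receptor of neural stem cells, was 1.82-fold higher (11.45 ± 0.05 against 10.59 ± 0.06, SD, n = 3; limma adjusted p = 0.0308), and Gfap is the other higher member, shared with the astrocyte list. Tnc, the matrix protein tenascin C, was 4.69-fold lower (−2.23, SE 0.28, limma adjusted p = 0.012). Sox2 (0.56, limma adjusted p = 0.285), Nes (−0.49, 0.364), Vim (0.07, 0.880), Hes5 (0.53, 0.216) and Egfr (−0.21, 0.600) did not pass. The list did not pass without GFP negative replicate 3 (median 0.32, camera adjusted p = 0.113). The call of Nr2e1 held only without GFP negative replicate 3 (otherwise limma adjusted p at most 0.150). That of Gfap was lost without GFP positive replicate 1, 2 or 3 (at most 0.0999) and that of Tnc without GFP positive replicate 1 or 3 (at most 0.0784).

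**Figure D3:**
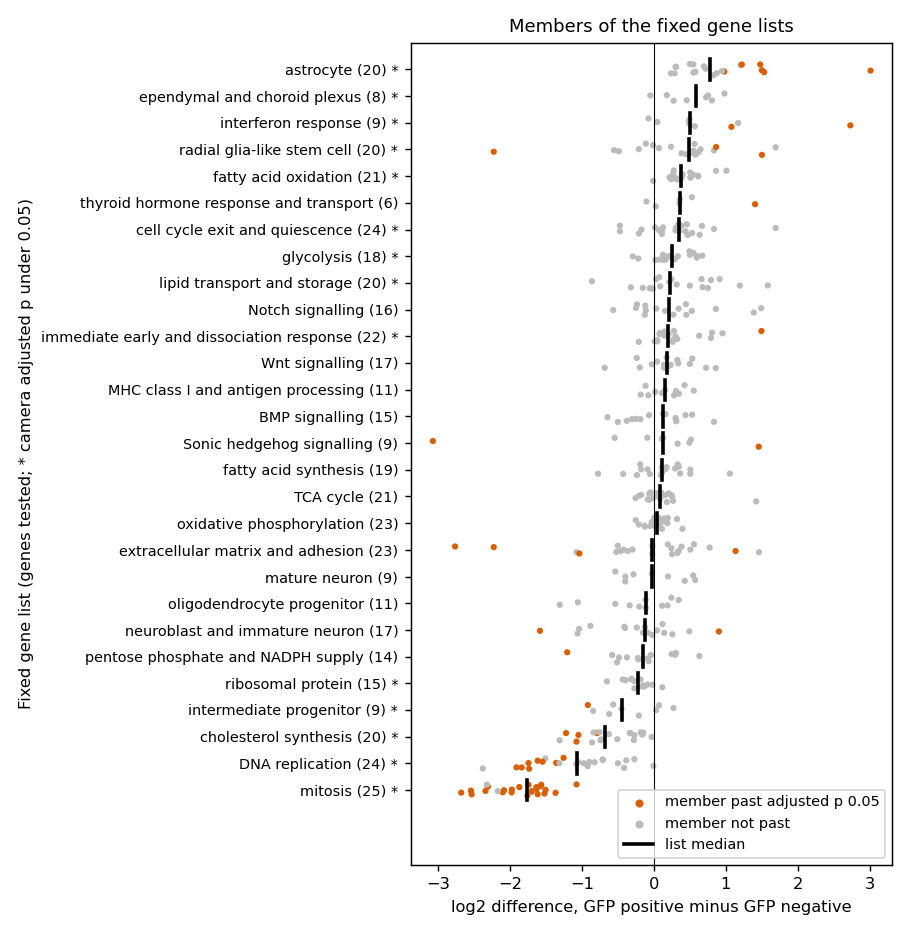
Difference between the groups (GFP positive minus GFP negative, log2, horizontal axis) of each measured member of the gene lists with at least 5 tested genes. Points are genes, orange where past the limma threshold; bars are list medians, from −1.76 for mitosis to 0.77 for astrocyte markers, and an asterisk marks a camera adjusted p under 0.05.

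Among markers of later stages of neurogenesis, those of intermediate progenitors passed as a list and those of neuroblasts and neurons did not. Intermediate progenitor markers were lower as a list (9 measured of 17 on the array, 6 negative and 3 positive, median −0.45). The camera adjusted p was 0.0318, or 0.251 with an estimated correlation. Elavl2 fell by 0.92 (limma adjusted p = 0.0463), and 4 members were lower when adjusted over the list alone. That list was past the threshold no longer without GFP positive replicate 2 (camera adjusted p = 0.0519), GFP negative replicate 1 (0.136) or GFP negative replicate 2 (median −0.17, 0.0663). Eomes, a marker of these progenitors, measured 3.61 ± 0.57 and 3.87 ± 0.79 (SD, n = 3) and was not tested. Of 17 measured neuroblast and immature neuron genes, 1 rose (Rnd2, 0.90) and 1 fell (Elavl4, −1.59), 1 and 2 when adjusted over the list alone, and the list did not pass (median −0.12, camera adjusted p = 0.181). Neurod1 differed by −1.06 (limma adjusted p = 0.0796) and Prox1 by 0.12 (0.903), or −0.37 at its probe set with the smallest p. Dcx (2.43 and 2.42) and Tubb3 (3.31 and 3.40) lay near background in both groups. Mature neuron markers did not pass (9 measured, median −0.03, mean 0.01, camera adjusted p = 0.758), with 2 higher at an unadjusted p under 0.05. Oligodendrocyte progenitor markers did not pass either (11 measured, median −0.12, camera adjusted p = 0.150); 1 was lower when adjusted over the list alone, the list passed with fry (adjusted p = 0.021), and Olig2 (−0.20) and Pdgfra (−0.54, limma adjusted p = 0.217) did not pass. The calls of Elavl2, Rnd2 and Elavl4 held only without GFP negative replicate 3 (otherwise limma adjusted p at most 0.196, 0.214 and 0.162), where 1 oligodendrocyte progenitor marker was higher and 1 lower.

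Few markers of other cell types rose above background. Only 2 of 19 microglia and macrophage markers on the array were tested, 3 of 18 endothelial, 3 of 18 pericyte and smooth muscle, 3 of 17 mature oligodendrocyte and 1 of 5 erythroid markers, too few for a list test. Among them Tmem88b, on the oligodendrocyte list, was 2.20-fold higher (limma adjusted p = 0.0463), and Acta2, the smooth muscle actin, was 2.44-fold lower (limma adjusted p = 0.0413); both were named after their values were seen, and neither passed without GFP positive replicate 1 or 3. Over the 6 fits with 1 array left out they passed in 1 and 2, with a limma adjusted p of at most 0.171 and 0.176. Ependymal and choroid plexus markers were higher as a list (8 measured, 7 positive, median 0.59; camera adjusted p = 0.0318; adjusted p = 0.379 with an estimated correlation), with 0 members past the limma threshold or when adjusted over the list alone, and 4 higher at an unadjusted p under 0.05. The brightest were Rarres2 (−0.05, or 0.24 without probe sets of cross-hybridising suffix) and Dynlrb2 (0.72, limma adjusted p = 0.220). GFP negative replicate 3 was at 0.45 for this list relative to each gene's mean, above the GFP positive arrays (0.11 to 0.33). The list was past the threshold no longer without GFP positive replicate 1 (median 0.39, camera adjusted p = 0.0821), GFP negative replicate 1 (0.42, 0.136) or GFP negative replicate 2 (0.27, 0.133), and without GFP negative replicate 3 its median was 0.89 and 2 members were higher. Every array read Xist at 12.6 to 12.8, while the brightest Y-linked probe set stayed at 2.87 to 3.70, which gives a single sex pattern across the 6 arrays.

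The genes nearest to the title of the series, those of fatty acid synthesis, did not differ as a list. Of 19 measured, 12 were positive (median 0.11, camera adjusted p = 0.303), and 0 passed when adjusted over the list alone. Fasn measured 9.39 ± 0.15 in GFP positive and 9.57 ± 0.53 in GFP negative cells (SD, n = 3), a difference of −0.18 with a 95% interval of −0.84 to 0.48 (limma adjusted p = 0.813). Acaca, which supplies malonyl-CoA, differed by −0.19 (interval −1.11 to 0.73), Mid1ip1, a relative of Thrsp, by 0.35 (−0.20 to 0.90), Scd2 by 0.36 (−0.05 to 0.78) and Acly by −0.09. Without GFP negative replicate 3, which was the brightest array for Fasn, Fasn differed by 0.11 and Acaca by 0.25, neither past the threshold. There 16 of 19 members were positive, 1 other member was lower, and 3 were higher and 2 lower at an unadjusted p under 0.05 by limma. With array weights 16 were positive (median 0.27, camera adjusted p = 0.198) and 1 member was higher. Over the arrays left out the list median ran from 0.061 to 0.16, and the list never passed with camera.

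Cholesterol synthesis genes were lower, with all 20 measured members negative and a median of −0.68 (1.60-fold lower; camera adjusted p = 6.25e-08; adjusted p = 0.251 with an estimated correlation). After adjustment over all genes 4 fell (Stard4, Fdft1, Hsd17b7 and Idi1), and 10 did when adjusted over the list alone. Fdft1, squalene synthase, was 2.11-fold lower (9.72 ± 0.26 against 10.80 ± 0.23, SD, n = 3; limma adjusted p = 0.0376). Stard4, a sterol transport protein and not a synthesis enzyme, was 2.33-fold lower (limma adjusted p = 0.0308). The number of members past the threshold was 0 without any 1 of the GFP positive replicates or without GFP negative replicate 2, where 9 or 10 were lower at an unadjusted p under 0.05. It was 1 without GFP negative replicate 1 and 6 without GFP negative replicate 3, and the list passed the camera threshold in each fit (median −0.79 to −0.46). The limma adjusted p of Stard4 and Fdft1 was at most 0.127 and 0.172 over the arrays left out.

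Fatty acid oxidation genes were higher as a list, 20 of 21 positive with a median of 0.37 or 1.30-fold (camera adjusted p = 0.000263; adjusted p = 0.289 with an estimated correlation). No member passed the limma threshold or when adjusted over the list alone, and 6 were higher at an unadjusted p under 0.05; the brightest were Hadh (0.31, SE 0.44) and Eci2 (0.37, SE 0.23). Cpt1a, which admits fatty acids to mitochondria, differed by 0.24 (limma adjusted p = 0.721), and by −0.0190 without probe sets of cross-hybridising suffix. Without GFP negative replicate 3, 5 members of the list were higher and the median was 0.51. Lipid transport and storage genes were higher as a list (20 measured, median 0.23; camera adjusted p = 0.0435; adjusted p = 0.346 with an estimated correlation), with 0 past the limma threshold and 5 higher and 1 lower when adjusted over the list alone, the same counts as at an unadjusted p under 0.05. Its brightest members, the fatty acid binding proteins Fabp7 (−0.01) and Fabp5 (0.07), and Mlycd, malonyl-CoA decarboxylase (0.09), did not pass. Nearest to the threshold, and named after their values were seen, were Clu (0.91, limma adjusted p = 0.0510), Abca1 (0.79, 0.0519), Mgll (1.19, 0.0537), Gpam (0.75, 0.0567) and Apoe (1.58, 0.0609). Of the 20 members 6 were negative, Dgat2 (−0.86, 0.111) among them. With trend and robust settings 5 members were higher. This list was past the threshold no longer without GFP positive replicate 1 (median 0.13, camera adjusted p = 0.0954), GFP negative replicate 1 (0.17, 0.136) or GFP negative replicate 2 (0.19, 0.0755), and without GFP negative replicate 3 its median was 0.58 and 5 members were higher.

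Other metabolic lists differed little. Glycolysis genes were higher as a list (18 measured, 16 positive, median 0.25; camera adjusted p = 0.0256; adjusted p = 0.251 with an estimated correlation), with 0 past the limma threshold or when adjusted over the list alone and 5 higher at an unadjusted p under 0.05. Aldoc differed by 0.55 (limma adjusted p = 0.160) and Ldhb by 0.20, and the list call was lost without GFP negative replicate 1 (median 0.20, camera adjusted p = 0.113); without GFP negative replicate 3, 2 members were higher. Pentose phosphate and NADPH supply genes did not pass (14 measured, median −0.15, camera adjusted p = 0.235), and 1 of them fell, also when adjusted over the list alone: Mthfd2, of mitochondrial folate metabolism, was 2.31-fold lower (limma adjusted p = 0.0425), a call that held only without GFP negative replicate 3 (otherwise at most 0.131). Neither did the TCA cycle (21 measured, median 0.08, camera adjusted p = 0.497) nor oxidative phosphorylation (23 measured, median 0.04, camera adjusted p = 0.646), which had 1 and 0 members higher and 0 lower at an unadjusted p under 0.05 by limma; without GFP negative replicate 3, 1 TCA cycle gene was higher. Ribosomal protein genes were lower as a list by a small amount (15 measured, 14 negative, median −0.22; camera adjusted p = 0.0195; adjusted p = 0.392 with an estimated correlation). None passed the limma threshold or when adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. The brightest, Rps9 and Rpl27, differed by 0.12 and −0.15. Rps9 differed by −0.81 without probe sets of cross-hybridising suffix, and also at its probe set with the smallest p among all probe sets. That list was past the threshold no longer without GFP positive replicate 1 (camera adjusted p = 0.0530) or GFP negative replicate 1 (0.136).

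Interferon response genes were higher as a list (9 measured, 8 positive, median 0.50; camera adjusted p = 0.000468; adjusted p = 0.192 with an estimated correlation). After adjustment over all genes 2 rose, and 4 did when adjusted over the list alone. Ifit3 was 6.64-fold higher (8.02 ± 0.32 against 5.29 ± 0.53, SD, n = 3; limma adjusted p = 0.00999) and Ifit2 was 2.11-fold higher (limma adjusted p = 0.0163). By limma 0 members passed without GFP positive replicate 1 or 3, with 3 and 4 higher at an unadjusted p under 0.05. The number was 1 without GFP positive replicate 2 or GFP negative replicate 2, 2 without GFP negative replicate 1 and 4 without GFP negative replicate 3. Ifit3 had a limma adjusted p of at most 0.0637 and Ifit2 of at most 0.0991 over the arrays left out. Genes of MHC class I and antigen processing did not pass (11 measured, median 0.15, camera adjusted p = 0.259), with 1 higher at an unadjusted p under 0.05. Immediate early and dissociation response genes were higher as a list (22 measured, 21 positive, median 0.20; camera adjusted p = 0.0126; adjusted p = 0.192 with an estimated correlation). Of these the heat shock gene Hspa1a rose 2.82-fold (limma adjusted p = 0.0192), also when adjusted over the list alone, and without GFP negative replicate 3 the list did not pass (camera adjusted p = 0.0659) although 3 members were higher. The call of Hspa1a was lost without any 1 of the GFP positive replicates or without GFP negative replicate 2 (limma adjusted p at most 0.100).

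No signalling list passed with camera in the comparison set as the main one, although single members differed and the thyroid hormone list passed under some alternatives. With fry, which does not compare a list with other genes, the thyroid hormone (adjusted p = 0.0175), Notch (0.0408) and Wnt lists (0.021) passed in the higher direction. In Sonic hedgehog signalling (9 measured, median 0.13, mean −0.08, camera adjusted p = 0.549) Gli2, a transcriptional effector, was 2.75-fold higher (limma adjusted p = 0.0192) and the coreceptor Cdon was 8.43-fold lower (−3.07, SE 0.38, limma adjusted p = 0.0116), at 2.85 ± 0.49, near background, against 5.93 ± 0.64 (SD, n = 3). Counts were 1 higher and 2 lower when adjusted over the list alone. In the thyroid hormone list (6 measured, median 0.36, camera adjusted p = 0.0551) Dio2, which activates thyroid hormone, was 2.65-fold higher (1.41, SE 0.21, limma adjusted p = 0.0162), and it alone passed when adjusted over the list alone. This list passed the camera threshold with the log2 6 filter (adjusted p = 0.04995), with trend and robust settings (0.0435) and with the 3′ to 5′ covariate (0.0451). Notch (16 measured, median 0.21, camera adjusted p = 0.164), Wnt (17 measured, 0.18, 0.148) and BMP signalling (15 measured, 0.13, 0.935) had 0 members past the limma threshold. They had 5, 2 and 2 higher and 1, 0 and 2 lower at an unadjusted p under 0.05, and 2, 0 and 0 higher when adjusted over the list alone. Extracellular matrix and adhesion genes went both ways (23 measured, median −0.02, camera adjusted p = 0.497). There Nid1 was 2.20-fold higher (limma adjusted p = 0.0159), while Lama4, under log2 4 in GFP positive cells, was 6.80-fold lower (0.0290) and Tnc and Vcan fell as well, with 1 higher and 3 lower when adjusted over the list alone. Calls of members in these lists were lost without GFP positive replicate 1 or 3. Without GFP positive replicate 2, those of Gli2, Dio2, Nid1 and Lama4 were lost, and without GFP negative replicate 2 those of Gli2, Cdon, Nid1 and Lama4 (limma adjusted p at most 0.129 in these fits). The call of Vcan held only without GFP negative replicate 3 (otherwise at most 0.139). Without GFP negative replicate 3 the counts were 2 higher and 1 lower for Sonic hedgehog and for Wnt signalling, 2 higher for the thyroid hormone list, 1 higher for Notch, 1 lower for BMP and 4 higher and 3 lower for extracellular matrix. Without GFP negative replicate 1 they were 1 higher for Notch and 2 higher and 3 lower for extracellular matrix.

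The genes with the largest differences were mostly outside the lists. Shisa9, an auxiliary protein of AMPA receptors, was 13.3-fold higher (7.12 ± 0.18 against 3.38 ± 0.11, SD, n = 3, limma adjusted p = 0.000843). It remained past the limma threshold whichever array was left out (adjusted p 0.00194 to 0.0184). Its only probe set above the filter carries a cross-hybridising suffix, so Shisa9 was not tested without such probe sets. Car10, a carbonic anhydrase-related protein, was 11.9-fold higher (limma adjusted p = 0.0086), and Gpc5, a glypican, 10.3-fold higher (0.00766), and like Shisa9 both were near background in GFP negative cells. Chil1, a chitinase-like protein, was 8.40-fold higher (8.66 ± 0.39 against 5.58 ± 0.83, SD, n = 3; limma adjusted p = 0.0147), and Pla2g7, a secreted phospholipase, 7.01-fold higher (0.00766). Abhd3, Cacna2d2 and Myrip were higher by 6.35-fold to 6.57-fold. Akr1c19, Rab3il1, Chst1, Slc25a34 and Bhlhe41 rose from a mean under log2 4 in GFP negative cells, near background, to means of 5.46, 6.04, 6.16, 6.06 and 5.52, so that their folds depend on the background correction. On the other side Nr5a2, a nuclear receptor, was 8.69-fold lower (2.23 ± 0.04 against 5.35 ± 1.06, SD, n = 3; limma adjusted p = 0.018), and Col18a1, a basement membrane collagen, 7.41-fold lower (0.0265). Htr3a, a serotonin-gated channel, was 7.22-fold lower (limma adjusted p = 0.0269), Dgkk, a diacylglycerol kinase, 7.07-fold lower (0.0141), Itga4, an integrin, 5.95-fold lower (0.0355) and Prokr1, a prokineticin receptor, 5.83-fold lower (0.0147). Nr5a2, Col18a1, Htr3a and Prokr1 lay under log2 4 in GFP positive cells, and their folds depend on the background correction too. Of these genes only Shisa9 passed without GFP positive replicate 1 or 3. Without GFP positive replicate 2 the calls of Chil1, Slc25a34, Myrip, Nr5a2, Col18a1, Htr3a and Itga4 were lost, without GFP negative replicate 1 those of Slc25a34, Htr3a and Itga4, and without GFP negative replicate 2 those of Chil1, Slc25a34, Myrip, Nr5a2, Col18a1, Dgkk and Itga4 (limma adjusted p at most 0.188 in these fits).

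**Figure D4:**
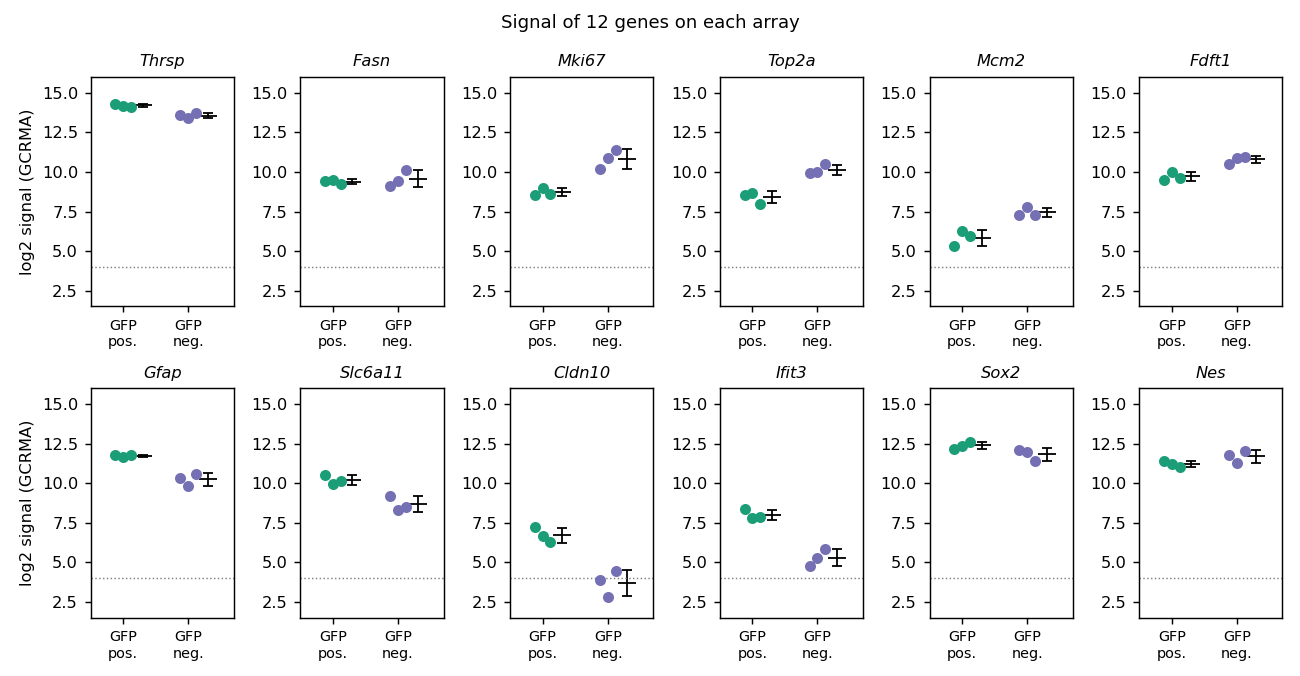
Log2 signal of 12 genes on each array (points; GFP positive left, GFP negative right), with the mean and SD of 3 arrays beside them in black and the filter level of log2 4 dotted. Mki67, Top2a, Mcm2 and Fdft1 lie lower and Gfap, Slc6a11, Cldn10 and Ifit3 higher on all GFP positive arrays, and Fasn overlaps between the groups.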

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

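The tests of explanations for the mitosis, Thrsp and interferon results were chosen only after the result was seen; the fixed lists, the leaving out of each array and the 10 splits of the arrays were set beforehand. Probe sets that the annotation assigns to no single gene stand outside the comparison of genes. Of 10092 such probe sets 3095 were tested, and 2 were higher and 1 lower in GFP positive cells. The higher ones read 7.87, 7.59 and 7.76 against 5.27, 4.78 and 4.37, and 6.47, 6.85 and 7.06 against 4.36, 4.15 and 4.11. The lower one read 2.49, 2.45 and 2.84 against 5.71, 5.64 and 5.18 (limma adjusted p = 0.0228 each).

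Mitosis genes were lower in GFP positive cells, and GFP negative replicate 3 alone is argued against as the cause, since without it the upper quartile of the 25 differences was −1.47, against −1.62 with all arrays. A trend in the 3′ to 5′ ratio between the arrays is also argued against, as the upper quartile was −1.61 with that covariate; that fit left 0 members past the limma threshold and 25 at an unadjusted p under 0.05. Other differences in RNA between the groups stay open, as the 18S control signal separated them (13.4 to 14.1 in GFP negative, 12.8 to 13.0 in GFP positive arrays, a gap of 0.35) and cannot be told apart from the group. A share of non-dividing astrocytes among the GFP positive cells stays open: 19 of 20 tested astrocyte markers were at or above log2 4 in GFP negative cells too, and neural stem cells share many of these markers, so they cannot be told apart here. A slower cycle of cells with the reporter signal may also underlie it and was not tested. The labels name only the reporter status as the difference between the groups.

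Thrsp, whose product the reporter stands for, differed by 0.65, less than many other genes. Compression of bright signal could account for part of this and stays open: the dimmer of the 2 bright probe sets differed by 0.24 more than the brighter (SE 0.09), in the direction compression predicts. GFP positive cells among the GFP negative ones would limit every ratio alike, and as the sole cause they are argued against by 61 genes past the threshold with an interval above that of Thrsp as measured; together with compression they stay open. A reporter signal that differs from the transcript in time or level, and a difference in Thrsp transcript that is small, both stay open and were not tested.

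The fixed interferon response list was higher in GFP positive cells (adjusted p = 0.192 with an estimated correlation). Microglia or macrophages as their source are argued against, since 19 markers of these cells had a median of 2.37 in GFP positive and 2.39 in GFP negative cells, near background. Both list members past the threshold belong to the Ifit family, and for them cross-hybridization within it stays open. The 7 other tested members of the list had a median of 0.49, with 0 past the limma threshold and 3 higher at an unadjusted p under 0.05. Their camera p was 0.0122, or 0.0898 with an estimated correlation. Outside the list, Gbp6, named after its value was seen, was also among the higher genes past the limma threshold. It shares a symbol stem with the list members Gbp2 and Gbp3, and its 2 probe sets differed by 2.18 and 2.23. Its call was lost without GFP positive replicate 1 or 3, and whether it shares a cause with the list was not tested. A higher interferon response of these cells may remain as a hypothesis, found and tested on the same arrays, and a difference in handling between the groups stays open, since the immediate early and dissociation response list was higher too (21 of 22 positive, camera adjusted p = 0.0126; adjusted p = 0.192 with an estimated correlation).

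The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 470 genes past the limma threshold (1917 at an unadjusted p under 0.05) and the highest other split 0 (1290 unadjusted), so that 1 of 10 splits gave as many. For gene lists the real split gave 14 and the others 2 to 7, so that again 1 of 10 gave as many. Lists thus passed camera at the preset correlation under every split, also where the groups were mixed. A list past that threshold is therefore by itself weak ground for a difference between the groups.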

How the results depend on the processing

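The 3′ to 5′ covariate was chosen after seeing the data; the other tests in this part were set beforehand. Named genes whose direction turned and lists whose call changed are given by setting, and the cause was not tested unless stated. Other named genes that lost their call numbered 29 without a filter, 7 with all probe sets, 2 without cross-hybridising suffixes, 1 each with quantile normalization or a common median, 2 with trend and robust settings, 3 with array weights, 44 with the covariate and 10 to 49 without 1 array other than GFP negative replicate 3. Aldoc and S100b passed with all probe sets, each at its probe set with the smallest p. Aldoc and Ccnd1 passed with trend and robust settings, and Dynlrb2, Ccnd1 and S100b with array weights. Shisa9 kept its side under every alternative that tested it. It was not tested without cross-hybridising suffixes, since its only probe set above the filter carries one. The direction of the mitosis, DNA replication, cholesterol and astrocyte lists held under every alternative that uses the preset correlation. Without a filter 101 genes were lower, the lipid transport (0.087) and ependymal lists (0.050) did not pass, and camera's direction for the BMP list turned (0.024). With log2 6 as the filter the ependymal list (0.72) did not pass, the thyroid hormone list (0.36) did, and BMP turned (0.029). With all probe sets, read at the probe set with the smallest p, Rarres2 was 0.24, Rps9 −0.81 and Prox1 −0.37. Without cross-hybridising suffixes Rarres2 was 0.24, Rps9 −0.81 and Cpt1a −0.0190, and the glycolysis (0.21) and intermediate progenitor lists (−0.32) did not pass. With trend and robust settings Thrsp (0.65) and the thyroid hormone list (0.36) passed and ependymal genes (0.59) did not. With array weights, which gave GFP negative replicate 3 a weight of 0.152 and GFP positive replicate 2 one of 8.35, 1051 genes were higher, 603 lower and 8 lists passed. There Thrsp (0.70) passed (its adjusted p ran from 0.0144 to 0.336 over all alternatives), Fabp5 was −0.00484, Rarres2 0.27, Fasn 0.12, Acaca 0.14, Prox1 −0.10, BMP turned (0.18), and these lists did not pass: lipid transport 0.50, glycolysis 0.29, quiescence 0.26, radial glia 0.40, immediate early 0.13 and ribosomal −0.15. With the covariate 9 genes were higher and 0 lower (794 and 563 unadjusted by limma), Acly was 0.077, the lipid transport (0.26) and ependymal lists (0.30) did not pass, the thyroid hormone list (0.29) did, and oxidative phosphorylation (−0.013) and BMP (0.034) turned. With an estimated correlation 1 list passed; lost, at unchanged medians, were mitosis −1.76, DNA replication −1.07, cholesterol −0.68, intermediate progenitors −0.45, ribosomal −0.22, fatty acid oxidation 0.37, lipid transport 0.23, glycolysis 0.25, quiescence 0.34, radial glia 0.49, ependymal 0.59, immediate early 0.20 and interferon 0.50. Fry did not pass fatty acid oxidation 0.37, lipid transport 0.23, ependymal 0.59 or ribosomal −0.22, and passed the thyroid hormone list 0.36, Notch 0.21, Wnt 0.18 and oligodendrocyte progenitors −0.12. With the replicate block 19 genes were higher and 8 lower, with fewer degrees of freedom, 14 lists passed and mature neurons were at −0.0277. By limma 39 named genes past the threshold without the block were not past it there, and the mitosis, DNA replication, cholesterol, astrocyte and interferon lists had 0 members past it (25, 18, 9, 11 and 3 at an unadjusted p under 0.05). The main comparison was set without a block beforehand, as the labels name no batch. Same-numbered arrays deviated from their groups with correlations of −0.25, 0.05 and −0.50. With 3 arrays per group these values are linked and cannot decide whether the numbers mark pairs. Leaving out 1 array in turn, which leaves fewer arrays, gave 1 to 801 genes higher, 0 to 443 lower (0 by limma without GFP positive replicate 1 or 3, 702 and 529 unadjusted), 9 to 14 lists and Thrsp 0.57 to 0.72. Ranges were Acly −0.29 to 0.12, Hadh −0.14 to 0.64, Fabp7 −0.15 to 0.10, Fabp5 −0.067 to 0.17, Rarres2 −0.30 to 0.35, Rps9 −0.034 to 0.39, Rpl27 −0.32 to 0.010, Fasn −0.41 to 0.11, Acaca −0.57 to 0.25, Mlycd −0.39 to 0.56 and Prox1 −0.24 to 0.32. For lists they were BMP −0.043 to 0.23, oxidative phosphorylation 0.0088 to 0.11, lipid transport 0.13 to 0.58, glycolysis 0.20 to 0.29, quiescence 0.26 to 0.37, radial glia 0.32 to 0.50, intermediate progenitors −0.53 to −0.17, ependymal 0.27 to 0.89, immediate early 0.16 to 0.24 and ribosomal −0.32 to −0.14. Of the values sought, 20 could not be had, where a gene or list was not tested. Signal near background limits the folds of the 40 higher and 48 lower genes with a group mean under log2 4.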

Other observations

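The family tests in this part were chosen only after the result was seen, and the genes named here were chosen after their values were seen. Genes that share a symbol stem leaned to 1 side in several families: of 314 families with at least 5 tested genes, tested in both directions with Fisher's exact test, 7 passed. That test treats genes as independent, so its p-values can be too small for genes that vary together. The estimated correlation was 0.55 for the mitosis list and 0.30 for the DNA replication list. Several lower family members, E2f1, Kif11 and Mcm2 among them, stand on those lists, so the families partly restate them. Of 7 E2F transcription factors, which govern the cell cycle, 4 fell: E2f1 (−1.84), E2f2 (−1.26), E2f7 (−2.11) and E2f8 (−1.42; adjusted p = 0.00241 for the family). Of 28 kinesins 6 fell (adjusted p = 0.0035), among them Kif11 (−1.98), Kif18b (−2.13), Kif2c (−2.37) and Kif4 (−2.35), motors of the mitotic spindle. In the same family 2 rose, Kif1a (1.23) and Kif5a (1.16), motors of axonal transport; another probe set of Kif1a read −0.54. Of 9 Mcm genes 4 fell (adjusted p = 0.0035), and the Cdca (3 of 6 lower, 0.0222) and Cdc families (5 of 29 lower, 0.0327) also passed.

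On the higher side, 5 of 13 cytochrome P450 genes rose (adjusted p = 0.00241): Cyp4f15 (2.53), Cyp4f14 (1.82), Cyp1b1 (1.59), Cyp4v3 (1.44) and Cyp2j9 (1.12). Members of the Cyp4f and Cyp2j groups are known to oxidise fatty acids. Genes with the Car stem passed as well (3 of 7 higher, adjusted p = 0.0378 by Fisher's exact test). Car10 (3.57), a carbonic anhydrase-related protein, Car5b (1.91) and Car11 (0.95) were higher and Car3 (−1.90) was lower. These counts rest on the 470 genes past the threshold with all arrays. Without GFP positive replicate 1 or 3 only 2 and 1 genes passed by limma, with 760 higher and 702 lower, and 735 and 529, at an unadjusted p under 0.05.

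Apoe, a lipid carrier made by astrocytes and a member of the lipid transport and storage list, differed by 1.58 and did not pass (limma adjusted p = 0.0609).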
